A study of Mus musculus with 44 samples.

How the data were processed

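RNA from mouse intestine was measured by poly-A selected, strand-specific RNA sequencing in 44 libraries from 2 models of inflammatory bowel disease, with 23 libraries of the T cell transfer model and 21 of the TNFΔARE model. For each model the authors deposited a table of expected counts per gene, estimated reads rounded to whole numbers with no scaling, and a table of normalized signal. The submitters' processing notes name Salmon 0.14.1, DESeq2 without a version, and the builds mm10 and GRCm38. The aligner settings and the annotation release are not given in the sources used here. In the deposited normalized signal every value is the raw estimate times a factor of its own for each gene and library. Checked on genes above 20 reads in every library of a model, these factors had a geometric mean of 1 per gene.

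Each table holds 29720 genes, of which 29395 identifiers matched the reference annotation and 325 did not. In the transfer model 7435 genes were 0 in every library, and in the TNFΔARE model 8397. Library totals ran from 5.95 to 22.3 M counts (M, 10 to the power of 6) in the transfer model (median 17.7) and from 5.8 to 13.1 M in the TNFΔARE model (median 10.5). PCR reads without molecular identifiers are not independent molecules.

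Gene tests used the expected counts in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (15317 in the transfer model, 14370 in the TNFΔARE model), library sizes were scaled by TMM, and a quasi-likelihood model with robust estimation was fitted to all 4 groups of a model, with the group and the batch given by the labels as terms. Tests were two-sided quasi-likelihood F-tests with Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. Differences between the models were tested in a joint fit of 44 libraries with batch nested in model. Levels are counts per M library counts (CPM) on TMM-scaled library sizes, and fold changes are log2 values with their standard error (SE). Fitted fold changes are adjusted for batch, so they can differ from the ratio of mean CPM.

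Before the data were examined, the comparisons, the alternatives, 37 gene lists and the rule for named genes were fixed. Of 690 list entries, 687 matched a gene. Lists with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and list scores are mean log2 CPM with a prior count of 2. The marker lists stand for cell types that whole intestine can hold and identify no cell. The rule names 7 genes always (Tnf, Il6, Il1b, Cxcl1, Ptgs2, Mapkapk2, Zfp36), the 2 members past the threshold with the largest change from each of the 10 lists with the smallest p, and the 5 highest and 5 lowest fold changes among called genes with a mean of at least 1 CPM, without unnamed gene models, pseudogenes and antigen receptor segments. Where no gene passed, it names the 5 genes with the smallest p. Other members of the lists named in the text were chosen after their values were seen. Il6 fell below the count filter in both models.

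For each model, up to 200 genes per direction with the smallest p for inflammation were taken as sets and tested by camera in the inhibitor comparison of the other model. The alternatives were RLE scaling, DESeq2 1.42.0, limma-voom 3.58.1 with quality weights, no count filter, no batch term, a replicate block, the 2 compared groups alone, a single batch, each library left out in turn, the deposited normalized signal with limma after adding 1, a fold-change minimum, camera with an estimated correlation, fry, and sets of 50 genes. Leaving out 1 library with small intestinal transcripts, and leaving out that library with 5 that hold pancreatic transcripts, were added after the data were seen. Replicate numbers were not taken as a pairing across groups, so the block is given only among the alternatives. Same-numbered libraries correlated at over 0.1 in 3 of 4 pairs for the inhibitor in non-inflamed transfer mice (median 0.323). All 4 of these pairs shared a batch, which was not removed before correlating, so a pairing and a shared batch cannot be told apart. In every other comparison of 2 groups at most 2 pairs correlated at over 0.1.

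Ranges over the alternatives do not include the fits with each library left out in turn, whose changed calls are given apart.

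On counts simulated from the fitted means and dispersions, 200 changed genes were planted in groups of the same size and depth. The edgeR test recovered from 25 to 69% of genes changed 2-fold and from 82 to 90% of genes changed 4-fold over the 6 comparisons of groups, with 9 to 13 false calls. Planted genes had a mean of at least 1 CPM. Counts were drawn independently for each gene, without outlying libraries, so recovery in the real samples can be lower.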

Results

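The labels describe 8 groups of mouse intestine. In the T cell transfer model, mice without Rag1, which lack their own T and B cells, received 400000 naive T cells and developed colitis (inflamed) or 200000 bulk T cells (non-inflamed). In the TNFΔARE model, mice lacking an AU-rich element of the Tnf gene that limits the life of its mRNA (inflamed) stood beside wild-type littermates (non-inflamed). Mice received vehicle or ATI-450, an inhibitor of the kinase MK2 (gene Mapkapk2), at 3 mg/kg, were redosed 16 h later and were harvested 90 min after the second dose per the sample labels, where the series description gives 24 h of treatment. The transfer model had 6 inflamed vehicle, 5 non-inflamed vehicle, 6 inflamed inhibitor and 6 non-inflamed inhibitor libraries, and the TNFΔARE model had 5, 5, 6 and 5. Batch was spread unevenly: inflamed vehicle libraries of the transfer model were 1 from batch 3 and 5 from batch 4, against 2, 3 and 1 from batches 1, 3 and 4 with the inhibitor. In the TNFΔARE model inflamed vehicle libraries were 4 from batch 2 and 1 from batch 3, against 1 and 5 with the inhibitor. Non-inflamed vehicle libraries were 3 from batch 1 and 2 from batch 4 in the transfer model, and 5 from batch 2 in the TNFΔARE model. In the transfer model batch 3 held 5.95 to 7.16 M counts per library and batch 4 held 15.8 to 22.3 M.

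The models differed in region. Hoxb13, a transcription factor gene of the distal colon, read between 101 and 610 CPM in the transfer libraries with the exception of inflamed vehicle replicate 3, which read 0.0761 CPM, and at most 0.922 CPM in the TNFΔARE libraries. The small intestinal enterocyte list had a score of 10 in that replicate, 1.33 to 5.18 in the other transfer libraries and 7.71 to 10.17 in the TNFΔARE libraries.

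**Figure D1:**
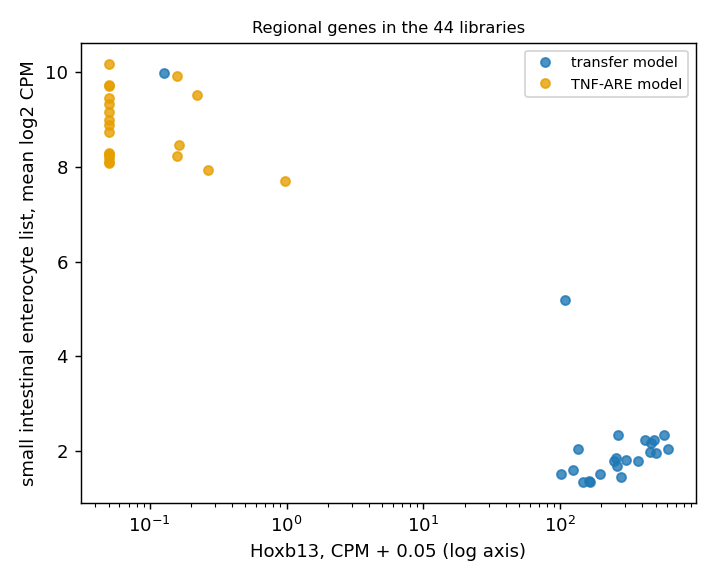
Mean log2 CPM of the small intestinal enterocyte list against Hoxb13 CPM plus 0.05 (log axis), 1 point per library, for 44 libraries coloured by model. Inflamed vehicle replicate 3 of the transfer model (score 10) lies among the TNFΔARE libraries.

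Transcripts of neutrophils, T cells and macrophages were higher in inflamed than in non-inflamed vehicle-treated transfer mice (n = 6 and n = 5), which also differ in the T cells they received. Of 23 measured neutrophil markers, 18 rose, 0 fell and 5 did not pass, and 20 were higher adjusted over the list alone. Mmp8, the neutrophil collagenase, rose by 7.81 ± 1.13 on the log2 scale (SE, adjusted p = 0.000215), from 0.0208 to 7.11 CPM. Stfa2l1, another of them, read 3.31 ± 5.21 CPM (SD) against no counts. Of 20 T cell markers, 15 rose (19 over the list alone), among them Cd2, an adhesion receptor, at 3.58 ± 0.69 (adjusted p = 0.00331) and Cd3d, a chain of the T cell receptor complex, at 3.60 ± 0.89 (adjusted p = 0.0116). Of 20 monocyte and macrophage markers, 14 rose (16 over the list alone), with Lyz2, lysozyme of myeloid cells, at 3.24 ± 0.69 (adjusted p = 0.00524) and Ly6c2, of inflammatory monocytes, at 4.58 ± 1.22 (adjusted p = 0.0167). These 3 lists passed with adjusted p = 9.62e-13, 1.03e-13 and 4.28e-12, and each had adjusted p = 0.143 with an estimated correlation.

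Members of other immune lists passed as well. Of 25 cytokine and early inflammatory mRNAs, most of them with AU-rich elements, 12 rose (20 over the list alone, adjusted p = 2.43e-09, adjusted p = 0.259 with an estimated correlation). The interleukin genes Il1a and Il1b, which encode interleukin-1, rose by 4.57 ± 0.79 (adjusted p = 0.00195) and 3.75 ± 0.94 (adjusted p = 0.0127), and the neutrophil-attracting chemokines Cxcl2 and Cxcl1 by 4.66 ± 1.24 (adjusted p = 0.0162) and 3.46 ± 1.08 (adjusted p = 0.0371). Tnf read 17.3 ± 10.8 CPM (SD) against 2.75 ± 3.19 and did not pass (2.53 ± 0.87, adjusted p = 0.0568), and Ptgs2, cyclooxygenase-2, did not pass either (1.15 ± 0.40, adjusted p = 0.0574). Without inflamed vehicle replicate 3 both passed (adjusted p = 0.0218 and 0.0247), as they did without non-inflamed vehicle replicate 7 (adjusted p = 0.0089 and 0.0208). Tnf also passed without inflamed vehicle replicate 2 (0.0455). Cxcl1 did not pass without inflamed vehicle replicate 1 (0.0735), 4 (0.0507), 5 (0.0564) or 6 (0.0665), or without non-inflamed vehicle replicate 1 (0.0589), 2 (0.0653) or 6 (0.135). Without non-inflamed vehicle replicate 7 the changes were 7.71 for Cxcl2, 5.93 for Cxcl11, 5.41 for Cd3d and 4.18 for Tnf. Over the alternatives Tnf had adjusted p from 7.21e-05 to 0.566 and Ptgs2 from 0.000933 to 0.577. Of 16 Th1 and Th17 effector genes 10 rose (13 higher and 1 lower over the list alone, adjusted p = 2.98e-08), with Batf, a transcription factor of Th17 cells, at 3.48 ± 0.61, and of 19 matrix metalloproteinase and stromal inflammation genes 12 rose (15 over the list alone, adjusted p = 1.57e-09), with Mmp3, stromelysin, at 5.09 ± 0.95 and Spp1, osteopontin, at 5.10 ± 1.12. Of 9 lymphoid tissue stroma genes 8 rose (8 over the list alone, adjusted p = 2.23e-07), with Madcam1, the gut homing addressin, at 3.25 ± 0.56. Each of these 3 lists had adjusted p = 0.143 with an estimated correlation. Of 30 interferon gamma response genes 4 rose (4 over the list alone, adjusted p = 7.25e-09, adjusted p = 0.353 with an estimated correlation), with Cxcl11, a T cell chemokine gene annotated as a polymorphic pseudogene, at 3.43 ± 0.93. Mapkapk2 rose by 0.46 ± 0.12 (adjusted p = 0.0147), and Zfp36, a destabilizer of AU-rich mRNAs, did not pass (0.13 ± 0.30, adjusted p = 0.799).

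Some smooth muscle and colonocyte genes also passed. Of 12 smooth muscle genes 7 fell (10 over the list alone, adjusted p = 2.23e-07), with Myh11, smooth muscle myosin, at -1.48 ± 0.36 (adjusted p = 0.0114). Of 20 colonocyte genes 7 fell and 1 rose (9 and 1 over the list alone, adjusted p = 3.09e-07): Sycn, syncollin, fell by 4.18 ± 1.14 on the log2 scale (adjusted p = 0.0187), while Guca2b, uroguanylin, rose by 3.67 ± 0.89 (adjusted p = 0.0107) and by 1.92 without inflamed vehicle replicate 3. Both lists had adjusted p = 0.143 with an estimated correlation. Without that replicate, whose Car1 was 0.457 CPM against 224 to 668 in the other inflamed vehicle libraries, 11 colonocyte genes fell and 1 rose (list adjusted p = 5.93e-07, adjusted p = 0.131 with an estimated correlation). Without the libraries with pancreatic transcripts as well, 1 fell and 1 rose (list adjusted p = 6.02e-06). Klb, a coreceptor for fibroblast growth factors, and Hao2, a peroxisomal oxidase, were among the lowest called (-4.82 ± 0.78 and -4.52 ± 1.27, the second -7.79 without inflamed vehicle replicate 2). Cyp2c69 read no counts in inflamed against 4.94 ± 4.85 CPM (SD) in non-inflamed mice. Of 15 small intestinal enterocyte genes 6 passed as higher (10 over the list alone, list adjusted p = 0.0513), and the score of this list in inflamed vehicle replicate 3 was 10. Without that library Sis, sucrase-isomaltase, went from 10.11 ± 2.81 (adjusted p = 0.0189) to 0.61 (adjusted p = 0.823), Apoa1, an apolipoprotein, from 10.35 ± 3.29 (adjusted p = 0.0373) to 0.31 (adjusted p = 0.938), and the Paneth cell defensin Defa24 from 12.24 ± 2.56 to 6.45 (adjusted p = 0.0363). Over the alternatives the adjusted p ran from 0.00327 to 0.991 for Sis, from 0.0037 to 0.938 for Apoa1 and from 0.000315 to 0.607 for Defa24. Apoa1 also missed the threshold without inflamed vehicle replicate 1 (0.0547) or non-inflamed vehicle replicate 2 (0.0523), 6 (0.156) or 7 (0.0898), and Sis without non-inflamed vehicle replicate 6 (0.0864).

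In all, 1210 genes were higher and 962 lower of 15317 tested (918 and 634 by at least 2-fold). The total of 2172 became 3151 without inflamed vehicle replicate 3 and 1053 without that library and the 5 with pancreatic transcripts, both tried after the data were seen. In the second of these fits 20 of the 32 named genes called kept their call, 10 lost it and 2, Apoa1 and Sis, changed sign. The total became 685 without non-inflamed vehicle replicate 6, 1 of the 2 libraries of its group in batch 4. In that fit Il1b had adjusted p = 0.0632, Mapkapk2 0.114, Cxcl1 0.135, Cxcl2 0.0754, Cxcl11 0.0817, Ly6c2 0.0791, Myh11 0.0643, Sycn 0.106, Hao2 0.124, Guca2b 0.05, and Cyp2c69 0.0651. By edgeR the total was 0 with the 2 groups alone (1615 at an unadjusted p under 0.05) and 0 within batch 4 (1321), where 5 inflamed stand against 2 non-inflamed libraries. Batch 1 held no inflamed and batch 3 no non-inflamed vehicle library, so with the batch term both fits compare the groups within batch 4. They are therefore not 2 separate checks. In the fit of all 4 groups the batches are also linked through the inhibitor libraries. Limma-voom gave 6031, DESeq2 2692 and the fit without a batch term 3399.

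**Figure D2:**
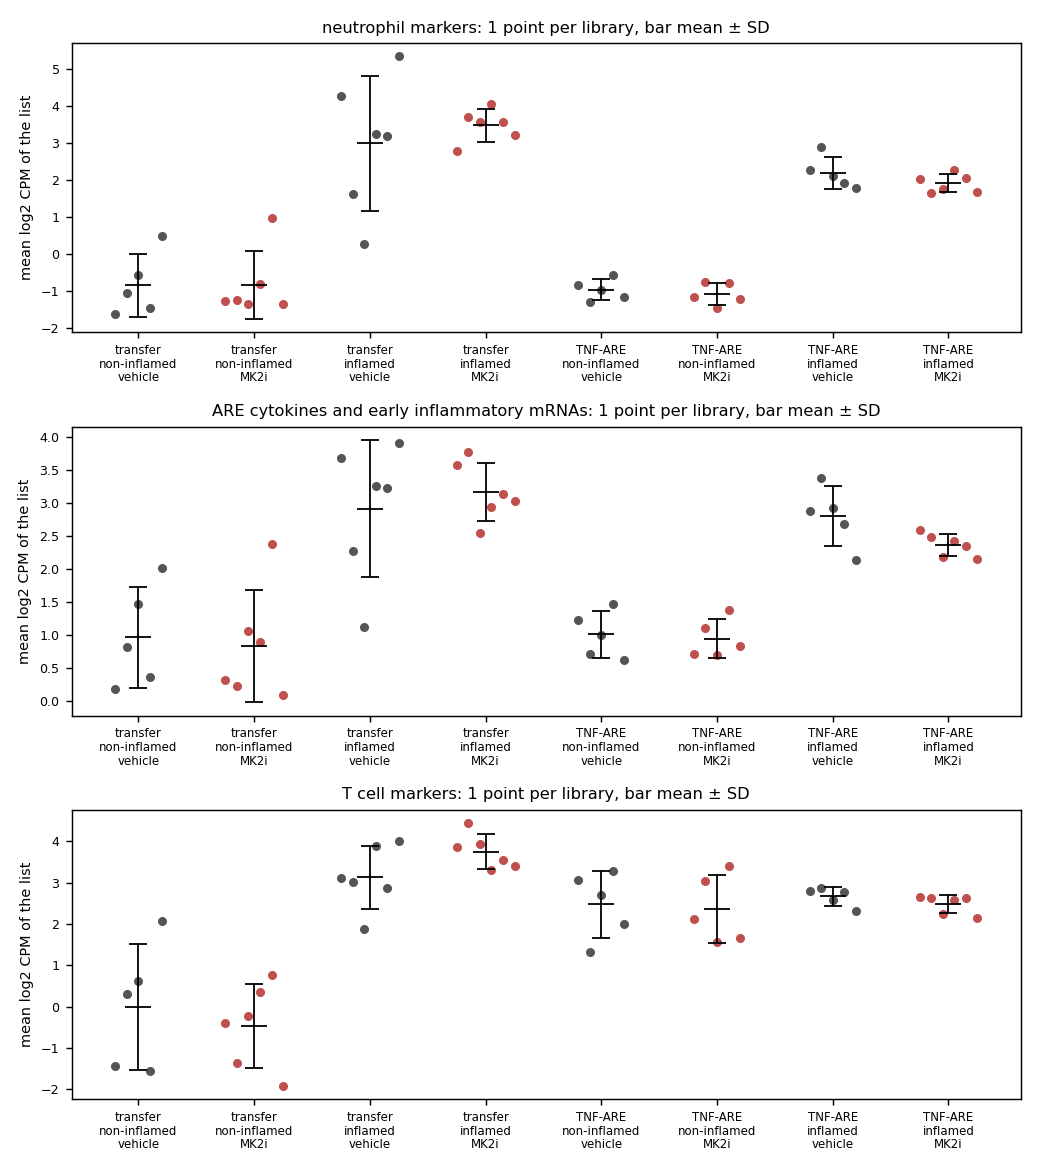
Mean log2 CPM of the neutrophil, cytokine and T cell lists, 1 point per library, with group mean and SD, for 4 groups in each model (red, inhibitor). The T cell score is 3.12 in inflamed and -0.01 in non-inflamed vehicle mice of the transfer model, and 2.67 and 2.48 in those of the TNFΔARE model.

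Inflamed TNFΔARE mice on vehicle (n = 5) differed from wild-type littermates (n = 5) in myeloid, cytokine and epithelial transcripts. Tnf itself (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007 on GRCm38) read 35.8 ± 15.2 CPM (SD) against 1.10 ± 0.533 and rose by 5.06 ± 0.41 (adjusted p = 1.16e-07). These mice carry the deletion in Tnf, so for this gene an effect of the deletion itself and of inflammation cannot be told apart. Of 17 neutrophil markers 15 rose (15 over the list alone), with S100a8 and S100a9, the calprotectin subunits, at 7.72 ± 0.48 (adjusted p = 1.52e-12) and 8.04 ± 0.56 (adjusted p = 5.39e-11). Of 22 cytokine and early inflammatory mRNAs 18 rose (18 over the list alone), including Cxcl5 at 6.41 ± 0.50, Cxcl1 at 5.5 ± 0.57, Il1b at 4.69 ± 0.54 and Ptgs2 at 1.53 ± 0.30 (adjusted p = 3.4e-08, 6.64e-08, 6.53e-06 and 0.00121). Of 20 monocyte and macrophage markers 17 rose and 1 fell (the same numbers over the list alone). Lyz2 rose by 3.68 ± 0.51 and Cd14, a lipopolysaccharide coreceptor, by 2.84 ± 0.21, and Mertk, a receptor for uptake of dying cells, fell by 1.08 ± 0.24. Of 17 matrix metalloproteinase and stromal inflammation genes 12 rose (12 over the list alone), with Mmp3 at 5.94 ± 0.47 and Chil1, a chitinase-like protein, at 5.26 ± 0.39. These 4 lists passed with adjusted p = 3.41e-49, 2.14e-25, 1.06e-22 and 2.44e-13, and with adjusted p = 0.000966, 0.00494, 0.0321 and 0.0295 with an estimated correlation. Of 20 T cell markers 0 passed, by edgeR over all genes and over the list alone (list adjusted p = 0.527).

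**Figure D3:**
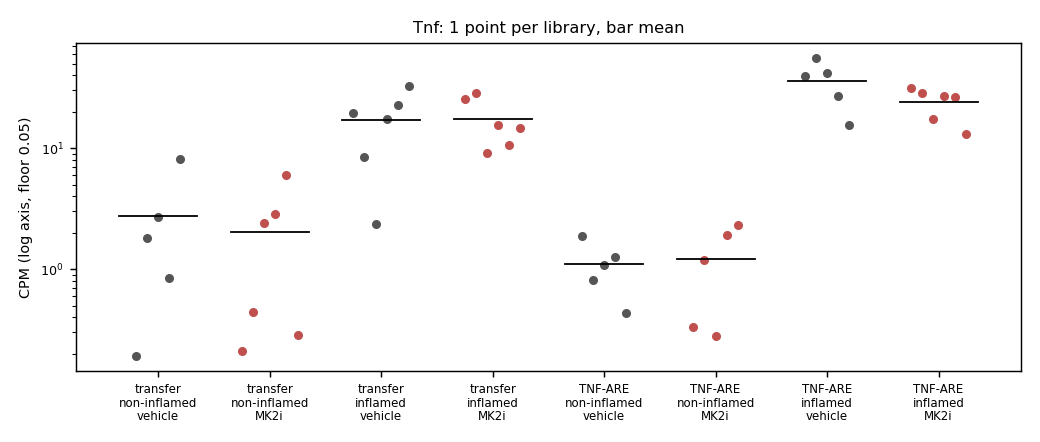
Tnf in CPM on a log axis, 1 point per library with the group mean, in 4 groups of each model (red, inhibitor). In the TNFΔARE model the means are 35.8 in inflamed and 1.10 in non-inflamed vehicle mice.

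Epithelial genes of this model moved both ways. Of 22 small intestinal enterocyte genes 13 fell (14 over the list alone, adjusted p = 4.42e-12, adjusted p = 0.106 with an estimated correlation), with Cubn, a receptor for intrinsic factor, at -2.32 ± 0.60 and Treh, trehalase, at -2.15 ± 0.32. In 3 of the 5 inflamed libraries the colonocyte gene Car1 read 747, 418 and 264 CPM (replicates 1, 3 and 5), against 8.03 and 1.16 in replicates 2 and 4. Whether tissue of the proximal colon in these 3 lowered the enterocyte genes was not tested. Of 28 xenobiotic and detoxification genes 15 fell and 2 rose (17 and 4 over the list alone, adjusted p = 1.41e-06, adjusted p = 0.368 with an estimated correlation), with Aldh1a1, a retinal dehydrogenase, at -2.78 ± 0.29 and Cyp2d26 at -2.65 ± 0.49. Of 23 fatty acid oxidation genes 7 fell (11 lower and 1 higher over the list alone, adjusted p = 7.6e-05, adjusted p = 0.376 with an estimated correlation), with Angptl4, a lipoprotein lipase inhibitor, at -2.66 ± 0.38 and the coactivator Ppargc1a at -1.38 ± 0.31. Of 20 epithelial antimicrobial and interleukin-22 response genes 8 rose and 2 fell (9 and 2 over the list alone, adjusted p = 7e-04, adjusted p = 0.368 with an estimated correlation): Saa3, a serum amyloid, rose by 7.48 ± 0.54 and Retnlb, a goblet cell resistin, by 4.73 ± 1.17, while the antimicrobial lectins Reg3a and Reg3b fell by 2.44 ± 0.36 and 2.35 ± 0.63. Of 11 lymphoid tissue stroma genes 6 rose (7 over the list alone, adjusted p = 4.75e-06, adjusted p = 0.376 with an estimated correlation), with Clu at 3.11 ± 0.49 and Tnfsf11, RANK ligand, at 2.99 ± 0.51. Of 14 Paneth cell genes 1, Lyz1, fell (5 over the list alone, adjusted p = 1.25e-05, adjusted p = 0.465 with an estimated correlation) by 1.49 ± 0.44 (adjusted p = 0.0264). The solute transporters Slc5a12 and Slc6a18 were among the lowest called (-3.48 ± 0.44 and -3.49 ± 0.49), with Unc93a2 and Unc93a (-3.85 ± 0.43 and -3.47 ± 0.65). The water channel Aqp8 was among the highest (6.87 ± 7.70 against 0.0145 ± 0.0323 CPM (SD), adjusted p = 0.0031), with counts in 3 of the 5 inflamed libraries. Over the alternatives the adjusted p ran from 0.00172 to 0.398 for Aqp8, from 0.00028 to 0.288 for Retnlb and from 0.00413 to 0.165 for Lyz1.

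In all, 1244 genes were higher and 1044 lower of 14370 tested (889 and 479 by at least 2-fold), a total of 2288. The total was 1275 with the 2 groups alone and 1310 within batch 2, the only batch that held both groups. Mapkapk2 rose by 0.35 ± 0.11 (adjusted p = 0.0365) but not past the threshold without inflamed vehicle replicate 1 (adjusted p = 0.144), inflamed vehicle replicate 2 (0.129) or non-inflamed vehicle replicate 3 (0.0639). Lyz1 did not pass without inflamed vehicle replicate 1 (0.0613) or non-inflamed vehicle replicate 4 (0.0617). Over the alternatives Mapkapk2 had adjusted p from 0.0103 to 0.155.

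Across 13925 genes tested in both models, 482 rose in both against 93.73 under independence, 102 fell in both against 58.81, and 55 and 23 were called in opposite directions. The fold changes had Pearson's r = 0.339 and Spearman's rho = 0.319 across genes, which are not independent replicates. The models also differ in region and in their non-inflamed mice, which a direct test cannot tell from a different response to inflammation. By that test the effect of inflammation differed for 821 of 15565 genes, 524 with a higher and 297 with a lower fold change in the transfer model. Of 20 T cell markers 10 had the higher change there (adjusted p = 4.34e-16, adjusted p = 0.319 with an estimated correlation), with Cd3d at 3.63 above the TNFΔARE model, and 3.94 without inflamed vehicle replicate 3. Without that library and those with pancreatic transcripts Cd3d did not pass (3.87, adjusted p = 0.0592). Cd14 had the lower change (-2.09). Of 22 small intestinal enterocyte genes 16 had the higher change in the transfer model (adjusted p = 7.49e-09, adjusted p = 0.687 with an estimated correlation), where the list score of inflamed vehicle replicate 3 was 10. Without that library Sis went from 11.83 to 2.55 (adjusted p = 0.349), Apoa1 from 10.89 to 1.18 (0.786) and Cubn from 8.19 to 1.47 (0.518), while Treh, at 8.08 before, passed at 3.69, but not without the libraries with pancreatic transcripts as well (2.16, adjusted p = 0.0654). In all 654 genes differed without replicate 3, without it and the libraries with pancreatic transcripts 337, both tried after the data were seen, and without a batch term 1430.

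The inhibitor in inflamed transfer mice (n = 6 against n = 6 vehicle) was compared to see whether blocking MK2, which stabilizes AU-rich mRNAs, lowers inflammatory transcripts. Tnf read 17.4 ± 7.93 CPM (SD) with the inhibitor and 17.3 ± 10.8 with vehicle, a log2 difference of 0.11 ± 0.88 (95% confidence interval -1.73 to 1.95). Il1b was at -0.09 ± 0.84 (interval -1.84 to 1.66), Cxcl1 at -0.47 ± 0.94, Ptgs2 at 0.05 ± 0.39, Zfp36 at 0.02 ± 0.30 and Mapkapk2 at -0.04 ± 0.12, with adjusted p of at least 0.99. Over the alternatives Tnf ran from -1.61 to 0.68, Il1b from -1.46 to 0.04 and Cxcl1 from -2.30 to 0.32, with the lowest values under a replicate block, and none of them passed. Of 25 cytokine and early inflammatory mRNAs 0 passed over all genes or over the list alone (list adjusted p = 0.404), and of 23 neutrophil markers 0 passed (list adjusted p = 0.901, median -0.22 with the test pointing up). Without inflamed vehicle replicate 3 the cytokine list was lower (adjusted p = 0.016), and had adjusted p = 0.999 with an estimated correlation. With a replicate block both lists were lower (adjusted p = 2.82e-08 for the cytokine and 2.15e-09 for the neutrophil list), as were interferon gamma response genes (2.34e-07), which did not pass without it (0.735). Correlations of same-numbered libraries, from -0.323 to 0.254, were over 0.1 in 2 of 6 pairs. Batch was not removed and only the pair numbered 6 shared one, so these correlations cannot decide whether the numbers are a pairing. Of 15 small intestinal enterocyte genes 0 passed over all genes, and 12 were lower over the list alone (list adjusted p = 4.91e-11, adjusted p = 0.967 with an estimated correlation), beside the score of 10 in inflamed vehicle replicate 3 against 1.33 to 2.05 with the inhibitor. Without that library the list had adjusted p = 4.21e-07 (adjusted p = 0.116 with an estimated correlation), and without the libraries with pancreatic transcripts as well 0.752. Goblet cell genes were higher (0 of 16 passed, adjusted p = 0.00405) and fibroblast and matrix genes (0 of 20) and smooth muscle genes (0 of 12) lower (adjusted p = 0.0142 for both), each with adjusted p = 0.967 with an estimated correlation and 0 members over the list alone. Without the batch term fibroblast genes were higher (adjusted p = 0.0119), and smooth muscle (0.418, pointing up) and goblet cell genes (0.324) did not pass. With a replicate block fibroblast (0.453) and smooth muscle genes (0.495, pointing up) did not pass.

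A single gene passed by edgeR in these mice, with 530 at an unadjusted p under 0.05 (766 under no difference). Nrn1 (ENSMUSG00000039114, chromosome 13, 36725361 to 36735131), which encodes neuritin, an anchored surface protein of neurons, fell by 3.76 ± 0.58 on the log2 scale (interval -4.97 to -2.56, adjusted p = 0.0136), from 1.00 ± 0.505 CPM (SD) to 0.16 ± 0.241. Limma-voom called 1 gene and DESeq2 5. The count was 1 without inflamed vehicle replicate 3 and 0 without it and the libraries with pancreatic transcripts. Nrn1 did not pass without the batch term (-2.29, adjusted p = 0.408), without inflamed inhibitor replicate 1 (0.139) or 6 (0.0928), or without inflamed vehicle replicate 1 (0.26), and its adjusted p ran from 1.55e-05 to 0.881 over the alternatives. No batch held 2 libraries of each group, so no fit within a single batch was run.

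**Figure D4:**
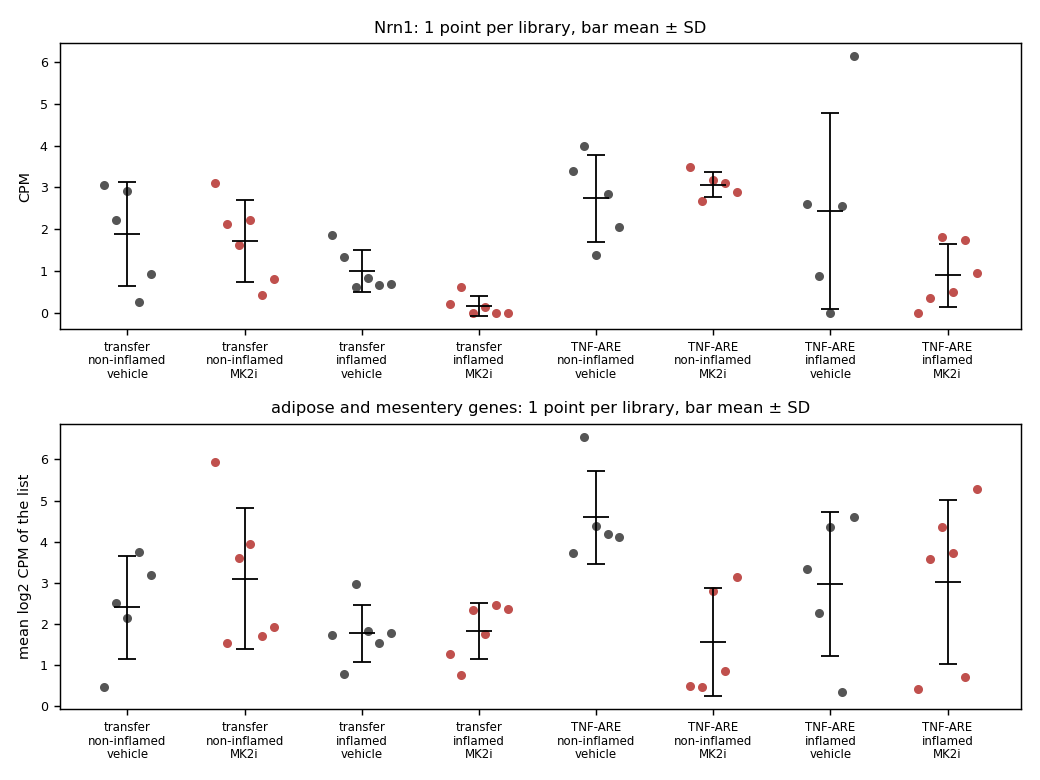
Nrn1 in CPM (top) and mean log2 CPM of the adipose list (bottom), 1 point per library with group mean and SD (red, inhibitor). Nrn1 has a mean of 0.16 CPM in inflamed inhibitor and 1.00 in inflamed vehicle mice of the transfer model, and the adipose score is 1.56 in inhibitor and 4.59 in vehicle non-inflamed mice of the TNFΔARE model.

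In inflamed TNFΔARE mice (n = 6 inhibitor, n = 5 vehicle) 0 genes passed by edgeR, with 216 of 14370 at an unadjusted p under 0.05, while DESeq2 called 1 and limma-voom 3. Tnf was at 0.06 ± 0.39 (interval -0.74 to 0.87) and Il1b at 0.15 ± 0.60 after adjustment for batch. Mean levels were 24.1 ± 7.13 (SD) against 35.8 ± 15.2 CPM and 26.9 ± 10.1 against 47.2 ± 40.5 CPM. Without the batch term the changes were -0.57 (adjusted p = 0.35) and -0.81 (adjusted p = 0.345). The mutated Tnf of these mice lacks the AU-rich element, so its level is no clear readout of an action through that element. Of the 7 genes always named, Zfp36 had the smallest p (-1 ± 0.29, adjusted p = 0.989). Nrn1 was at -2.78 ± 0.67 (adjusted p = 0.81, and -7.01 without inflamed vehicle replicate 5) and Cd33, a myeloid inhibitory receptor, at 3.53 ± 0.78 (adjusted p = 0.383, and 8.12 without inflamed inhibitor replicate 1). Ddx46 was at 0.99 ± 0.25 and Ust at 1.71 ± 0.47 (adjusted p = 0.989 for both). Klhl28 read no counts with vehicle and 1.66 ± 0.989 CPM (SD) with the inhibitor (adjusted p = 0.666). The smallest adjusted p, 0.0649, was shared by 2 immunoglobulin segments, Igkv1-115 and Ighv7-4. Of 22 cytokine and early inflammatory mRNAs 0 passed (list adjusted p = 0.771, median 0.08 with mean and test pointing down), while the list was lower without the batch term (adjusted p = 0.00268). Oxidative phosphorylation genes (0 of 25, adjusted p = 5.47e-05) and small intestinal enterocyte genes (0 of 22, adjusted p = 0.00011) were lower, both with adjusted p = 0.843 with an estimated correlation and 0 members over the list alone. Batch 2 held 1 inhibitor and 4 vehicle libraries and batch 3 held 5 and 1, so no fit within a single batch was run. Without the batch term 0 genes passed with 2354 at an unadjusted p under 0.05. The count was 2 without inflamed inhibitor replicate 3 or inflamed vehicle replicate 5.

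Genes that rose with inflammation in the other model stood as sets for the inflammatory program. In inflamed transfer mice, 194 genes that rose in TNFΔARE mice were higher with the inhibitor (adjusted p = 1.57e-05, median log2 change 0.18) and 184 that fell there were lower (adjusted p = 1.4e-18, median -0.66), with adjusted p = 0.47 and 0.314 with an estimated correlation. Without inflamed vehicle replicate 3 the medians were 0.03 (adjusted p = 0.687) and -0.09 (adjusted p = 0.000324). In inflamed TNFΔARE mice, 184 genes that rose in transfer mice were higher with the inhibitor (adjusted p = 0.00221, median 0.14) but had adjusted p = 0.968 with an estimated correlation and pointed down without a batch term (median -0.06, adjusted p = 0.301). The 170 genes that fell there did not pass (adjusted p = 0.888, and 2.99e-05 without a batch term).

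In non-inflamed mice the inhibitor left 0 genes past the threshold by edgeR in either model. In the transfer model (n = 6 inhibitor, n = 5 vehicle) 222 genes had an unadjusted p under 0.05, DESeq2 called 8 and limma-voom 0. Tnf was at -0.56 ± 0.91 and Il1b at -0.57 ± 0.92. Without non-inflamed inhibitor replicate 5, whose Il1b was 11 CPM against 0.263 to 0.959 in the other 5, they were at -1.23 and -1.69. Without non-inflamed vehicle replicate 7 they were at 0.36 and -0.06. The smallest p belonged to Jchain, the joining chain of secreted immunoglobulins (-2.80 ± 0.76), Nup205, a nuclear pore protein (-5.66 ± 1.60), Pla2g4c (6.19 ± 1.85, and 3.22 without non-inflamed inhibitor replicate 3), Muc13, a membrane mucin (-0.47 ± 0.15), and Sec11c (-0.95 ± 0.29), all with an adjusted p of 1. Heat shock genes were lower (0 of 12 passed, 0 over the list alone, adjusted p = 3.4e-07, adjusted p = 0.414 with an estimated correlation). In the TNFΔARE model (n = 5 and n = 5, all of batch 2) 411 genes had an unadjusted p under 0.05, DESeq2 called 16 and limma-voom 0. Hp (ENSMUSG00000031722, chromosome 8, 109575128 to 109579172), haptoglobin, read 0.854 ± 0.668 CPM (SD) with the inhibitor against 11.6 ± 11 (-3.73 ± 0.61, adjusted p = 0.094, and 0.00801 without non-inflamed vehicle replicate 1), with Timp4 at -2.44 ± 0.49, Serpina3c at -2.94 ± 0.65, Trf, transferrin, at -2.32 ± 0.55 (-1.07 without non-inflamed vehicle replicate 2) and Nnat at -1.21 ± 0.29. Over the alternatives Hp had adjusted p from 4.72e-08 to 1, and 1 gene passed without non-inflamed vehicle replicate 1 or 3. Of 10 adipose and mesentery genes 0 passed over all genes and 9 were lower over the list alone (list adjusted p = 2.78e-21, adjusted p = 0.0418 with an estimated correlation, adjusted p = 0.308 by fry), with Adipoq, adiponectin, at -3.86 ± 1.14. The score of this list was 6.56 in non-inflamed vehicle replicate 2 and 3.73 to 4.38 in the other 4 vehicle libraries.

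Whether the response to the inhibitor differed between inflamed and non-inflamed mice was tested as an interaction, in which 0 genes passed by edgeR in either model. In the transfer model 339 genes had an unadjusted p under 0.05 (DESeq2 called 9, limma-voom 1), with Nrn1 at -3.55 ± 0.68 (adjusted p = 0.296), Sec11c at 1.80 ± 0.43, Siglech, a receptor of plasmacytoid dendritic cells, at 2.29 ± 0.60, Tspoap1 at 2.37 ± 0.63 and Tnf at 0.67 ± 1.11. In the TNFΔARE model 252 did (DESeq2 called 3, limma-voom 0), with Hp at 3.74 ± 0.83, Abcb1b, a drug efflux pump, at 2.44 ± 0.66, Cd33 at 5.05 ± 1.41 (9.64 without inflamed inhibitor replicate 1, 8.84 without non-inflamed inhibitor replicate 4), Plppr5 at 2.19 ± 0.60, Zfp36 at -1.35 ± 0.37 and Tnf at 0.00 ± 0.65, all with an adjusted p of 1. Gbp4 read no counts in non-inflamed inhibitor mice. Between the models the inhibitor effect in inflamed mice differed for 1 gene of 15565 (589 at an unadjusted p under 0.05), Sult6b2, a sulfotransferase gene (-9.85 ± 1.33, adjusted p = 3.94e-05), which read 65.1 CPM in inflamed vehicle replicate 1 of the transfer model and at most 0.0761 CPM in the other 5 of that group. DESeq2 called 71, the fit without a batch term 54, the fit without inflamed vehicle replicate 3 12, and the fit without it and the libraries with pancreatic transcripts 0.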

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

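The tests of the 3 patterns below were chosen after the results were seen, with the exception of thinning the reads for Nrn1, and the splits of the samples were also described after the results.

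The first pattern is the small intestinal transcripts of inflamed vehicle replicate 3 of the transfer model. Its enterocyte list score was 10, against 7.71 to 10.17 in the TNFΔARE libraries and 1.33 to 5.18 in the other transfer libraries. A colon sample with a small share of small intestine is argued against by the distal colon genes, whose median log2 ratio to the other inflamed vehicle libraries was -7.63. A TNFΔARE library under this label is argued against by the B cell and plasma cell list, at -1.90 in this library, -2.33 to -1.27 in the other transfer libraries and 1.32 to 5.68 in TNFΔARE libraries. A small intestinal sample of a transfer mouse may explain it, and no label gives the region of each library. Replicate 3 need not be the only transfer library with such transcripts. Without it Defa24 still passed for inflammation (6.45, adjusted p = 0.0363), while Sis (0.823) and Apoa1 (0.938) did not. Whether the libraries with pancreatic transcripts also hold small intestinal ones was not tested.

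The second pattern is the lower Nrn1 with the inhibitor in inflamed transfer mice, which rests on 0 to 10 counts per inhibitor library and 8 to 27 per vehicle library. Few reads in the shallow libraries were tested by thinning every library to the smallest total, where the change was -5.02 (adjusted p = 0.0485). The change thus did not go away at equal depth. Thinning lowers counts that were already this low, so it cannot exclude an effect of few reads. A difference between batches stays open, as batch was spread unevenly over the groups compared. Without the batch term the change was -2.29 (adjusted p = 0.408, and 1.55e-05 to 0.881 over the alternatives) and with it -3.76, which cannot decide this. An effect of the inhibitor in inflamed mice stays open too, with an interaction at adjusted p = 0.296 and -2.78 (adjusted p = 0.81) in inflamed TNFΔARE mice, or -7.01 (adjusted p = 0.864) there without inflamed vehicle replicate 5.

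The third pattern is the lower adipose list with the inhibitor in non-inflamed TNFΔARE mice. A single library is argued against: with each left out in turn, the list median nearest to 0 was -2.15, without non-inflamed vehicle replicate 2. Less adipose tissue in the inhibitor libraries may explain it and stays open, as 8 adipocyte genes outside the list had a median of -1.58, from -4.24 for Thrsp to 0.21 for Aqp7. Nnat (-1.21), which is among the 8, was already named above for its small p in this comparison. An effect of the inhibitor shared by both models was not shown, with a list median of 2.27 in non-inflamed transfer mice. How much mesentery each sample held was not tested.

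In 104 tests, each of 1 measure in 1 of the 8 groups, 9 found a sample that stands apart. The measures are not independent, and 1 library appears under several of them, so no rate under chance is set beside this number. In the non-inflamed inhibitor group of the transfer model, replicate 5 had a total of 6.78 M counts (others 16.3 to 18.8), 11 CPM of Il1b (others 0.263 to 0.959) and a neutrophil score of 0.97 (others -1.35 to -0.81). Il1b read 117 CPM in inflamed vehicle replicate 2 of the TNFΔARE model (others 14 to 40.1). The small intestinal enterocyte score was 2.05 in inflamed inhibitor replicate 3 of the transfer model (others 1.33 to 1.6) and 7.71 in inflamed inhibitor replicate 1 of the TNFΔARE model (others 8.09 to 8.3). The pancreas acinar score was -0.77 in non-inflamed inhibitor replicate 1 (others -1.85 to -1.54) and -0.07 in non-inflamed vehicle replicate 7 (others -1.94 to -1.75) of the transfer model. The adipose score was 6.56 in non-inflamed vehicle replicate 2 of the TNFΔARE model (others 3.73 to 4.38). These tests did not pick out the enterocyte score of 10 in inflamed vehicle replicate 3 of the transfer model. They also missed pancreas acinar scores of up to 11.14 in that model. A second high library in a group can hide the first, so the tests do not find every unusual sample.

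The effect of inflammation differed between the models for 821 genes by the joint test, and that of the inhibitor in inflamed mice for 1, Sult6b2 (-9.85). Among inflamed vehicle libraries of the transfer model Sult6b2 was high only in replicate 1, a library with pancreatic transcripts. Without inflamed vehicle replicate 3 it was at -9.89 (adjusted p = 1.84e-05). Without the libraries with pancreatic transcripts as well it was at -0.67 and did not pass. For inflammation, the joint test cannot tell a different response from differences in region or in the non-inflamed mice. Named genes with a higher change in the transfer model were Cd3d (3.63), Spp1 (5.90), Guca2b (3.84), Defa24 (13.39), Lyz1 (7.36), Aldh1a1 (3.53), Angptl4 (4.57), Slc5a12 (12.92), Treh (8.08), Unc93a2 (10.80), Apoa1 (10.89), Sis (11.83), Cubn (8.19), Cyp2d26 (3.67), Slc6a18 (5.74) and Unc93a (11.28). Those with a lower change were Sycn (-5.43), Zdhhc1 (-5.07), Aqp8 (-10.08) and Cd14 (-2.09). Without inflamed vehicle replicate 3 of the transfer model, the last 6 of the higher genes no longer passed, and others moved, among them Treh to 3.69, Unc93a2 to 5.07, Defa24 to 8.14, Guca2b to 2.09 and Zdhhc1 to -9.97. Without the libraries with pancreatic transcripts as well, Cd3d (adjusted p = 0.0592), Defa24 (0.607), Angptl4 (0.106), Slc5a12 (0.631), Treh (0.0654), Unc93a2 (0.325) and Sycn (0.0509) did not pass either.

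Other splits of the same samples into groups of the same sizes were made, 100 per comparison with the real split among them. Counts as large came in 2 for inflammation in the transfer model (real 2172, highest other 2992) and in 2 for inflammation in the TNFΔARE model (2288, 2975). Counts as large were thus rare among these splits. The splits exchange libraries across batches, and in each model another split gave more genes, so chance is not excluded. In the transfer model the highest other split exchanged only inflamed vehicle replicate 3 and non-inflamed vehicle replicate 4. In the TNFΔARE model the highest other split kept 6 labels as in the real split. Chance cannot be excluded for the lists past the threshold in these comparisons (15 splits, real 22, highest other 27, and 22 splits, real 21, highest other 24). For the difference between models in inflammation 10 splits gave as many (821, 4448), and for that in the inhibitor effect 56 (1, 163).

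For the inhibitor, chance cannot be excluded for the results with a real value above 0 that follow. Nrn1 and the adipose list were not tested in this way by themselves. In inflamed transfer mice 14 splits gave as many genes (1, highest other 864) and 99 as many lists (4, 24), and the sets from the other model had p as small in 62 splits (1.57e-05, 4.77e-44) for genes that rose and 47 (7.01e-19, 1.37e-40) for genes that fell. In inflamed TNFΔARE mice 39 splits gave as many lists (12, 21), and for the sets the numbers were 50 (0.00111, 1.19e-22) and 97 (0.888, 1.16e-06). In non-inflamed mice as many lists came in 47 splits of the transfer model (14, 23) and 69 of the TNFΔARE model (13, 23), and for the interactions in 79 (10, 23) and 34 (17, 23). A real count of 0 genes is met by all 100 splits by construction, so the splits say nothing about chance for the gene counts of the inhibitor in inflamed TNFΔARE mice (highest other 16), in non-inflamed mice (576 in the transfer and 3816 in the TNFΔARE model) or of the interactions (2108 and 1). Some splits gave several times a real count above 0, such as 864 and 163 (real 1 each) and 4448 (real 821). What sets these apart was looked at for the first only. What sets apart the splits with 576, 2108 and 3816 genes was not tested. The split with 864 genes puts the 4 libraries of batch 3 on 1 side and 5 of the 6 of batch 4 on the other. The remaining library of batch 4 is inflamed vehicle replicate 3, the library with small intestinal transcripts. The batch term stayed in that fit, and no fit within a single batch was run there, so batch and region were not told apart.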

How the results depend on the processing

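Counts in this part follow the comparisons of the report, and the cause of a change was not tested. A value uncalled both ways counts as unchanged whatever its sign. Under RLE scaling all 32 named genes called for inflammation in the transfer model and all 31 in the TNFΔARE model stayed called.

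With limma-voom, inflammation in the transfer model gave 6031 genes (2104 shared with 2172), its interaction 1 and the inhibitor in inflamed TNFΔARE mice 3. With DESeq2, the inhibitor gave 5 genes in inflamed and 8 in non-inflamed transfer mice, 1 and 16 in TNFΔARE mice, interactions of 9 and 3, and a between-model inhibitor count of 71. Without a count filter the inhibitor in inflamed transfer mice gave 3 genes. A minimum of 2-fold left 1368 genes for inflammation in the TNFΔARE model.

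With the 2 groups alone, inflammation gave 0 genes in the transfer model (1615 at an unadjusted p under 0.05) and 1275 in the TNFΔARE model, and the inhibitor in inflamed transfer mice 0 (167). Within a single batch, inflammation gave 0 (1321) and 1310. Only batch 4 in the transfer and batch 2 in the TNFΔARE model held both vehicle groups. With the batch term, both fits thus compare the groups within that batch. No fit within a single batch was run for the inhibitor in inflamed mice or the interactions, as no batch held 2 libraries of each group, and Nrn1 fell below the filter with the 2 groups alone.

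Without the batch term, inflammation in the transfer model gave 3399 genes (2048 shared), and the between-model counts were 1430 and 54. The inhibitor then moved 12 lists in inflamed and 7 in non-inflamed transfer mice. Directions reversed in inflamed transfer mice for type I interferon (adjusted p = 0.000675), fibroblast (0.0119) and smooth muscle genes (0.418), in non-inflamed ones for fibroblast genes (0.483), in inflamed TNFΔARE mice for Paneth cell (0.0228), smooth muscle (0.0497) and adipose genes (0.807) and genes that rose in the other model (0.301), and in the TNFΔARE interaction for cytokine (0.0393) and Paneth cell genes (0.0484). Genes that fell in the other model passed in inflamed TNFΔARE mice (2.99e-05), where 2354 genes had an unadjusted p under 0.05, against 216 with the term.

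With a replicate block, inflammation in the transfer model gave 6130 genes (1928 shared), and the inhibitor moved 14 lists in inflamed and 8 in non-inflamed transfer mice and the TNFΔARE interaction 10. Apoa1 reversed (-1.66). With the inhibitor in inflamed transfer mice neutrophil (2.15e-09), monocyte (0.0286), T cell (0.00306), Th1 and Th17 (0.05), interferon gamma (2.34e-07), proliferation (0.029), oxidative phosphorylation (0.00195) and smooth muscle genes (0.495) reversed, and in non-inflamed ones T cell (0.945), Th1 and Th17 (0.0173) and interferon gamma genes (0.00019). In the transfer interaction cytokine (4.95e-05), neutrophil (6.04e-06), monocyte, T cell and smooth muscle (0.0161 each), Th1 and Th17 (0.00848), regulatory T cell (0.189), lymphoid stroma (0.152), interferon gamma (5.58e-09), interleukin-22 (0.396), xenobiotic (0.269) and fatty acid oxidation genes (0.234) did, and in inflamed TNFΔARE mice fibroblast genes (0.659).

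With an estimated correlation 0 lists passed in the transfer model, of 22 for inflammation, 4 and 14 for the inhibitor in inflamed and non-inflamed mice and 10 for the interaction. In the TNFΔARE model 4 of 21, 0 of 12, 1 of 13 and 0 of 17 did. The sets from the other model had adjusted p = 0.47 and 0.314 in transfer mice and 0.968 in TNFΔARE mice. With fry 0 lists passed for the inhibitor and the interaction in either model.

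Leaving out the library with small intestinal transcripts, inflammation gave 3151 genes, 7 lists passed with the inhibitor in inflamed transfer mice (0 in the 4 comparisons with an estimated correlation), the between-model inhibitor count was 12, genes that rose in the other model had adjusted p = 0.687, and type I interferon genes reversed in the transfer interaction (0.000168). Leaving out the libraries with pancreatic transcripts as well, the counts were 1053 (883 shared), 0 for the inhibitor (582), 337 and 0 between models, and the sets had adjusted p = 0.872 and 0.0608. Apoa1 (-2.82) and Sis (-2.34) reversed, as did type I interferon genes in inflammation (0.728) and the interaction (1.44e-06).

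With each library left out in turn, inflammation gave 685 to 3151 genes in the transfer model and 1747 to 2697 in the TNFΔARE model, the inhibitor 0 to 1 in inflamed and 0 to 0 in non-inflamed transfer mice and 0 to 2 and 0 to 1 in TNFΔARE mice, and both interactions 0 to 0. The 1 gene was lost without inflamed inhibitor replicate 1 or 6 or inflamed vehicle replicate 1.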

Other observations

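In 3 of the 5 inflamed TNFΔARE libraries on vehicle 2 genes of colonic epithelium, picked after the values were seen, read high, while Hoxb13 stayed at 0.922 CPM or less in this model. Carbonic anhydrase Car1 read 747, 8.03, 418, 1.16 and 264 CPM in inflamed vehicle replicates 1 to 5 and at most 5.98 CPM in the 10 non-inflamed libraries. Aqp8 read 17.2, 12.8 and 4.54 CPM in replicates 1, 3 and 5 and had no counts in replicates 2 and 4. Retnlb, which passed in the test of inflammation, read 3.6 to 64.2 CPM in the 5 replicates. Of 18 colonocyte genes measured, 3 rose, Car1 and Aqp8 among them, and 2 fell (3 and 2 over the list alone, list adjusted p = 0.274, adjusted p = 0.661 with an estimated correlation). The libraries high in Car1 and Aqp8 were thus the same 3, and whether they hold changed epithelium or a piece of proximal colon was not tested.

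Clock genes also differed with inflammation in the TNFΔARE model. Of 18 circadian clock genes 7 fell, 3 rose and 8 did not pass (10 lower and 3 higher over the list alone, list adjusted p = 0.0416, adjusted p = 0.459 with an estimated correlation). The output factors Dbp, Hlf and Tef fell by 1.67 ± 0.47, 1.61 ± 0.44 and 1.29 ± 0.29, while Arntl, which drives them, rose by 0.78 ± 0.25 and Bhlhe40, a repressor, by 1.02 ± 0.19. Harvest times of day are not among the labels used here. In the transfer model 1 clock gene, Nfil3, rose (2.32 ± 0.61). Transcripts of mast cells and eosinophils rose there: of 8 measured 5 did (5 over the list alone, adjusted p = 0.0144, adjusted p = 0.143 with an estimated correlation), with the mast cell proteases Mcpt2 at 3.20 ± 0.88 and Mcpt1 at 2.77 ± 0.84. Of 18 components of the p38 and MK2 pathway, 2 rose and 1 fell in the transfer model (3 and 1 over the list alone, list adjusted p = 0.687) and 3 rose in the TNFΔARE model (3 over the list alone, 0.485). Mapkapk2 and Mapk11 (2.08 ± 0.52 and 1.84 ± 0.35) were among those that rose in both.

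Transcripts of exocrine pancreas stood out in 5 inflamed transfer libraries. Cpb1, a pancreatic carboxypeptidase, read 2690 and 39.4 CPM in inflamed vehicle replicates 1 and 5 and 830, 684 and 229 CPM in inflamed inhibitor replicates 3, 5 and 6, against at most 0.617 CPM in the other libraries. Ins2, insulin, read 22 CPM in the first of these and 9.02 and 16.6 CPM in inhibitor replicates 3 and 5. Pbsn, a gene of the prostate, read 726 CPM (14682 counts) in non-inflamed vehicle replicate 6 and 15.2 CPM in inflamed vehicle replicate 4 of the transfer model, and at most 0.146 CPM elsewhere. Non-inflamed vehicle replicate 6 is the library whose absence took the inflammation count to 685. It is also 1 of the 2 non-inflamed vehicle libraries of batch 4. Whether tissue beside the intestine was collected with these samples was not tested.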
